A study of Homo sapiens with 15 samples.

How the data were processed

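RNA sequencing was done on BT20 cells carrying 1 of 5 lentiviral inserts, with 3 dishes per insert and 15 libraries in all. Per the labels' protocols, the cells were grown in EMEM with 10% fetal bovine serum, RNA was taken from a confluent 10 cm dish with an RNeasy kit, libraries were made with the TruSeq Stranded mRNA kit, and sequencing was done on a NovaSeq 6000. Groups were taken from the sample labels: control (lacZ), wtETV6, and the fusions E2E3, E4E3 and E4E2. As far as the labels tell, the 3 dishes of a group came from 1 transduced pool, so the spread between dishes does not include the spread between independent transductions. Each construct is therefore confounded with its transduced line.

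Each library has a pair of deposited files. The first holds read counts per gene symbol that the authors deposited, made with featureCounts and an NCBI gene annotation per the file names, on genome build GRCh38.p13 per the submitters' processing notes, which also name limma. The second holds log2 values that the authors deposited as log2(TPM + 1), per the file names. The aligner, the versions, the strand setting of the counter and the gene lengths behind the TPM values are not given in the sources used here. A wrong strand setting would lower counts of genes that overlap another gene on the opposite strand. Per library, 2 to the power of the deposited value, less 1, summed to 1000000, and zeros stood at the same genes as in the counts. The count divided by TPM was scaled to the median ratio of its library. Over 16287 genes, the highest and lowest coefficients of variation of this ratio between libraries differed by 2.43e-14, so both files hold 1 measurement. The files hold 44613 rows, of which 12590 were 0 in all libraries. Some symbols have a second row with a numbered suffix, which marks another placement of the gene in the annotation: 5082 such rows for 2708 symbols, with 0.272 to 0.368% of the counts. They were kept as deposited in the main test. BCL2L14 is such a symbol, and its level is given as the sum of both rows.

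Total counts were 15421195 to 20701199 per library. A library with no count for a gene allows up to 3 counts of its total, which was 0.149 to 0.198 counts per 1000000 (CPM) over the control libraries. Such limits cover counting error only.

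Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. All 15 libraries entered a single fit with the group as its only term. Genes were filtered with filterByExpr (15634 genes kept), libraries were scaled by the trimmed mean of M values (TMM), and groups were compared by edgeR's robust quasi-likelihood test, which is two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.0148, a biological coefficient of variation of 12.2%. The 10 comparisons were each insert against control, each fusion against wtETV6 and the fusions against each other. Levels are TMM-normalized CPM with the SD over 3 dishes. Log2 fold changes carry standard errors from the fit. Genes called in the same direction in the 3 fusions against control were counted as shared calls. Fusion-only genes are those that were also called in that direction for each fusion against wtETV6. Shared calls were compared with 20 simulated sets in which no gene differed. The numbers of calls that 3 independent lists would share were computed from the lists' sizes.

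The 21 gene lists were fixed before the data were examined, with the groups, tests, comparisons, alternative settings and the rule for named genes. They cover mesenchymal genes of the epithelial-mesenchymal transition (EMT), epithelial junction and identity genes, basal and luminal breast genes, TGF-beta response, extracellular proteases and inhibitors, interferon-stimulated genes, antigen presentation, NF-kappaB targets, G2/M and mitosis, DNA replication, BCL2 family and apoptosis, tubulins with microtubule-binding proteins and drug efflux pumps, ERK pathway output, ETS factors, hypoxia and glycolysis, cholesterol synthesis, the unfolded protein and integrated stress response, and markers of fibroblasts, leukocytes and endothelial cells. Lists with at least 5 tested genes were tested against all other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Only 3 leukocyte markers were tested, so that list has counts alone. From 0 to 7 genes of a list also stand in another list. Of the 12 antigen presentation genes tested, 6 belong to symbols with a second row, more than in any other list. Their counts are split between rows in the main test.

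Named genes follow a rule. ETV6 and BCL2L14 are always given. Against control, the rule takes the 10 largest rises and 10 largest falls among called genes with at least 2 CPM in the higher group and no overlap of the dishes, which chance gives for 10% of genes. It takes 5 and 5 for the other comparisons, and 10 and 10 for the fusion-only genes by their mean change. From each list it takes the 4 members with the smallest adjusted p, and always CDH1, CDH2, VIM, FN1, EPCAM, SNAI1, SNAI2, ZEB1, ZEB2 and TWIST1. Symbols beginning LOC, LINC or MIR and antisense genes are not named. Genes outside the rule are marked as chosen after their values were seen. Some genes that the rule takes are not reported here.

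The test was tried on simulated data, with changes put into 67 genes at 1.5-fold, 67 at 2-fold and 66 at 4-fold. At a 4-fold change, 87.9% of the seeded genes were called, at 2-fold 73.1% and at 1.5-fold 43.3%, with 5 unchanged genes called among 15181 tested. The share at 4-fold missed the criterion first set for this check. After that result the criterion was restricted to genes over 2 CPM, where 98.1%, 88.9% and 52.7% were called at 4-fold, 2-fold and 1.5-fold. A 1.3-fold fall seeded in the stress list was called by camera at adjusted p = 8.774e-26 with 0 of the other lists called. The simulated genes were drawn independently, so this check does not cover correlation between the genes of a list.

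The settings fixed as alternatives were RLE size factors, upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, limma-voom, DESeq2 1.42.0, limma-trend on the deposited log2 TPM, a fit of only the groups compared, a replicate block, an adjusted p of 0.01, a change of at least 2-fold, and leaving out each library. After the data were seen, 2 more were added: counts of both rows of a symbol summed, and a correction for GC content per library. GC content came from GENCODE gene models, which covered 87.4% of the genes tested. Exon positions of ETV6 and BCL2L14 were taken from the same models on GRCh38, whose exon numbers were assumed to be those of the labels.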

Results

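BT20 is an established human cell line from a triple-negative breast carcinoma, a tumour type without hormone receptors or HER2 amplification. BCL2L14 and ETV6 are neighbours on chromosome 12 and are joined by rearrangement in some of these tumours. ETV6 is a transcriptional repressor of the ETS family and BCL2L14 is a member of the BCL2 family. The 15 libraries hold messenger RNA from BT20 lines with 5 lentiviral inserts, 3 dishes each: lacZ as the vector control, full-length ETV6 (wtETV6), and the fusions E2E3, E4E3 and E4E2. E2E3 joins BCL2L14 exon 2 to ETV6 exon 3, E4E3 joins exon 4 to exon 3, and E4E2 joins exon 4 to exon 2. The comparisons ask how each insert's line differed from the vector line, how the fusions differed from wtETV6, and whether the fusions differed among themselves. Total counts were 15421195 to 20701199 per library and 20806 to 22768 gene symbols had a count. The 10 most abundant genes took 4.37 to 4.91% of the counts. Values after a plus-minus sign are standard errors for log2 fold changes and SDs over 3 dishes for levels, which are TMM-normalized CPM. Since the dishes of a group share 1 transduced line as far as the labels tell, every p measures the spread between dishes. Unless another test is named, an adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and that of a list is from camera. "Rose" and "fell" are used of genes and lists past an adjusted p of 0.05.

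The inserted genes were read first. ETV6 lies on chromosome 12 at 11649854 to 11895402 and BCL2L14 at 12049844 to 12211084, both on the plus strand of GRCh38. ETV6 was at 111 ± 3.7 CPM in control, 1205 ± 53.6 in wtETV6, 1974 ± 119 in E2E3, 1677 ± 161 in E4E3 and 2510 ± 196 in E4E2. Against control it rose 10.8-fold in wtETV6 (log2 3.44 ± 0.09, adjusted p = 6.909e-14), 17.8-fold in E2E3, 15.1-fold in E4E3 and 22.6-fold in E4E2. Reads of the endogenous gene and of the insert fall on the same symbol. The fusions held more ETV6 RNA than wtETV6, by log2 0.71 ± 0.08 in E2E3, 0.48 ± 0.08 in E4E3 and 1.06 ± 0.08 in E4E2. BCL2L14 had no count in any control or wtETV6 library, where 3 counts would be 0.149 to 0.198 CPM. In the fusion libraries it had 127 to 256 counts in E2E3, 219 to 679 in E4E3 and 297 to 859 in E4E2. Setting the mean of each fusion group (9.62, 21.35 and 27.33 CPM) against 0.198 CPM, the highest limit of a control or wtETV6 library, BCL2L14 was at least 48.6-fold higher in E2E3, at least 108-fold in E4E3 and at least 138-fold in E4E2. All 15 libraries thus carried the inserts their labels name, as far as these genes tell fusions from the rest. BCL2L14 counts were 0.48 ± 0.14% of ETV6 counts in E2E3, 1.33 ± 0.9% in E4E3 and 1.06 ± 0.5% in E4E2. Without E4E3 replicate 3 the mean of E4E3 was 0.81%. By the annotated exons (BCL2L14 exon 2 ends at 12079738 and exon 4 at 12090849), the BCL2L14 part is 433 coding bases in E2E3 and 678 in the others. The ETV6 part is 1193 bases from exon 3, which starts at 11839140, and 1323 from exon 2, which starts at 11752450. The length ratios are 36.3%, 56.8% and 51.2%. By these lengths the joined coding parts make whole codons in E2E3 and E4E2 but not in E4E3. If the assumed exons are right, E4E3 thus joins ETV6 out of its reading frame. The inserted sequences were not examined.

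**Figure D1:**
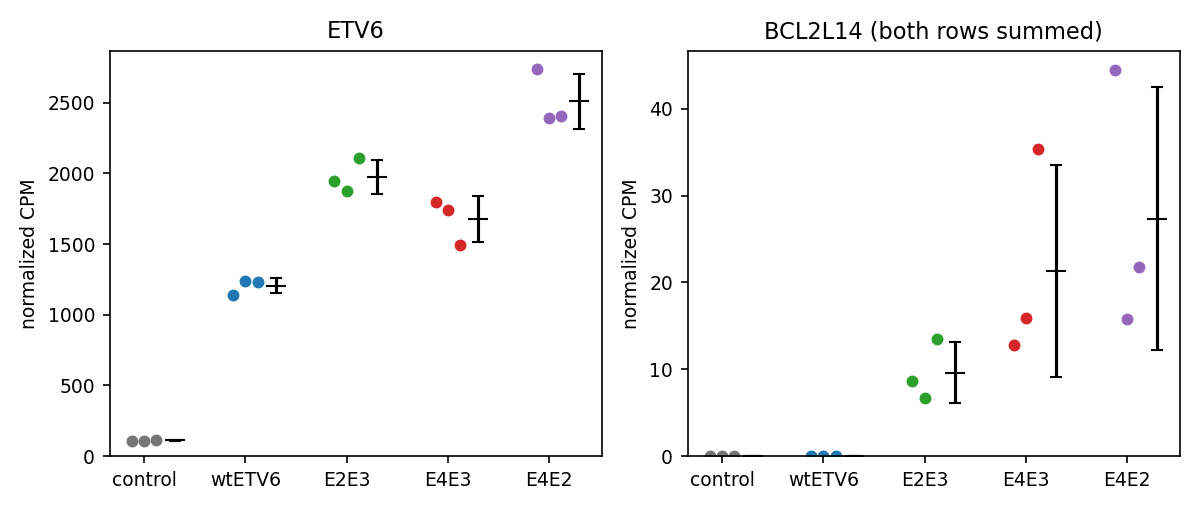
Normalized CPM of ETV6 and of BCL2L14 (both annotation rows summed) in each dish, with bars for the mean of 3 dishes and their SD. ETV6 stands at 111 CPM in control and at 1205 to 2510 in the other groups, and BCL2L14 has counts in the fusion groups alone.

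On the first principal component of log2 CPM, which held 51% of the variance, the fusion libraries lay at 19.8 to 38.5 and the control and wtETV6 libraries at -51.1 to -35.9. The second component held 10.9% and set E4E3 replicate 2 apart at 56.2, with E4E3 replicates 1 and 3 at 12.5 and -18.7. Between replicates 2 and 3 of E4E3 the squared differences were 99.78 times those of counting error, and 3.58 to 11.73 times in the other groups. The mitochondrial ribosomal RNA genes took 0.164% of counts in E4E3 replicate 2, 0.472 to 0.523% in E4E2 and 0.258 to 0.321% in control. Counts for E4E3 are therefore also given without replicate 2, which was chosen after the data were seen.

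**Figure D2:**
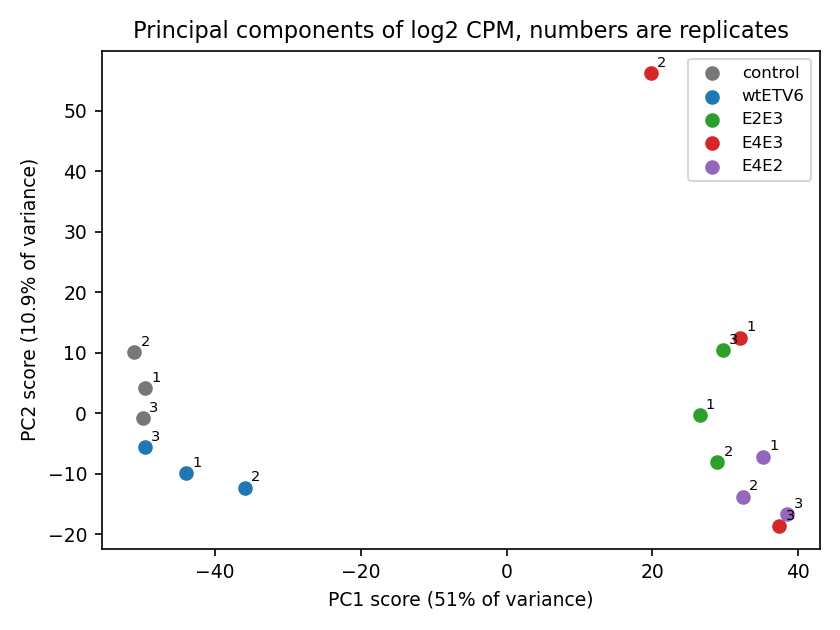
Scores of the 15 libraries on the first principal components of log2 CPM, 1 point per dish, with each axis giving its share of the variance. The fusion libraries lie at 19.8 or above on the first component, and E4E3 replicate 2 lies at 56.2 on the second.

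**Figure D3:**
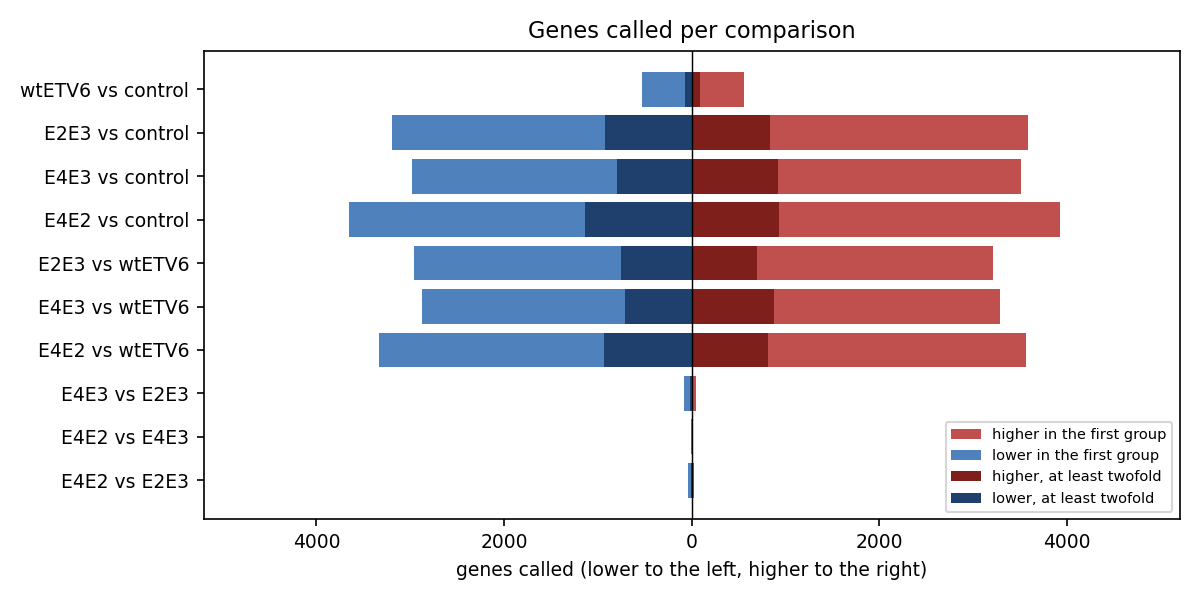
Genes called higher (right) and lower (left) in each of the 10 comparisons by edgeR at adjusted p under 0.05, with the part of at least 2-fold dark. The counts run from 20 for E4E2 against E4E3 to 7569 for E4E2 against control.

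In wtETV6 few genes were called beside the fusions. The largest rises in wtETV6 were of XG, a cell surface antigen (6.12-fold, log2 2.61 ± 0.39), KIAA1549L (4.94-fold), MUCL1, a small mucin (4.33-fold), PRLR, the prolactin receptor (4.28-fold), CD109, a membrane protein that binds TGF-beta (3.99-fold), and the protease inhibitor A2ML1 (3.65-fold). The list goes on with ARHGEF38 (3.3-fold), the cadherin CDH16 (3.19-fold) and WNT11, a secreted Wnt ligand (3.12-fold). PI3, an elastase inhibitor, fell most (12-fold lower, log2 -3.58 ± 0.47), with EDNRB, an endothelin receptor (6.7-fold lower), and DMBT1, a secreted mucosal scavenger receptor, from 361.1 ± 28 to 70.89 ± 12.5 CPM. PI3 stood at 0.159 ± 0.0874 CPM in wtETV6, where 3 counts are 0.152 to 0.175 CPM, so its fold is not exact. RARRES1, ZNF22, FAM107B, BPIFB1, ARL11 and the adrenergic receptor ADRA1D fell 2.93- to 3.71-fold. KLF15 also fell (log2 -1.54 ± 0.38), a call lost without control replicate 2 (adjusted p = 0.139) or wtETV6 replicate 3 (0.0947). In all, 555 genes rose and 528 fell of 15634 tested (6.9%), 91 and 71 of them at least 2-fold, at n = 3 dishes per group. Without control replicate 2 or 3 the count was 570 or 718, and without wtETV6 replicate 1 or 2 it was 648 or 641. With only these 6 libraries in the fit it was 2059. Falls outnumbered rises without control replicate 2 (278 rises and 292 falls), with only these 6 libraries (1002 and 1057) and with no filter on low counts (625 and 638).

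The stress list fell in wtETV6. Of its 24 genes 0 rose and 12 fell (19 adjusted over the list alone), with a median log2 of -0.56 (camera adjusted p = 4.545e-16, and 0.0466 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, stood at log2 -0.73 ± 0.12, PSAT1 of serine synthesis at -0.57 ± 0.09 and the cystine transporter SLC7A11 at -0.84 ± 0.14. Camera called 3 further lists, each lost with an estimated correlation. Of 24 basal genes 7 rose and 2 fell (7 and 3 adjusted over the list alone, p = 0.0392, and 0.542 with an estimated correlation), among them TRIM29 (log2 1.02 ± 0.13), KRT15 (0.73 ± 0.12) and, lower, CDH3 (-0.45 ± 0.07). Of 39 replication genes 3 rose (7 adjusted over the list alone, p = 0.00194, and 0.791 with an estimated correlation), led by RRM2 of nucleotide reduction (log2 0.63 ± 0.10). Of 15 NF-kappaB targets 0 rose and 2 fell (1 and 4 adjusted over the list alone, p = 0.0392, and 0.295 with an estimated correlation): the adhesion molecule ICAM1 (log2 -1.14 ± 0.12) and the cytokine LIF (-1.13 ± 0.18). Leaving out wtETV6 replicate 2 ended the basal, replication and NF-kappaB calls (camera adjusted p = 0.0796, 0.395 and 0.0518), and leaving out control replicate 3 ended the basal call (0.0776).

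No other list was called in wtETV6. Of 29 mesenchymal genes 1 rose and 4 fell (1 and 5 adjusted over the list alone), with a median of 0.05 that camera put lower. FSTL1, a secreted glycoprotein, fell (log2 -0.57 ± 0.12), as did fibronectin FN1 (-0.52 ± 0.12), whose call was lost without control replicate 1, wtETV6 replicate 1 or wtETV6 replicate 3 (0.0771, 0.0772 and 0.0783). The EMT genes VIM, SNAI1 and SNAI2 were at -0.18 ± 0.22, 0.25 ± 0.19 and 0.33 ± 0.24, and the epithelial genes CDH1 and EPCAM at 0.24 ± 0.07 and 0.04 ± 0.09, none of them called. CDH2, ZEB1, ZEB2 and TWIST1 had too few counts to be tested. Of 37 epithelial genes DSC2, a desmosomal cadherin, alone fell (log2 -0.91 ± 0.15; 2 and 3 adjusted over the list alone). Counts of rises and falls in the others were 2 and 3 of 27 TGF-beta response genes, 2 and 2 of 20 proteases and inhibitors, 2 and 3 of 37 interferon genes, 1 and 1 of 12 antigen presentation genes, 0 and 0 of 39 mitosis genes, and 1 and 0 of 25 apoptosis genes. Adjusted over the list alone these were 2 and 5, 5 and 4, 3 and 3, 1 and 1, 0 and 0, and 1 and 0. For the remaining lists they were 2 and 2 of 21 tubulins and efflux pumps, 0 and 4 of 24 ERK outputs, 1 and 2 of 21 ETS factors, 1 and 5 of 29 hypoxia genes, 0 and 3 of 24 cholesterol genes, 0 and 1 of 13 luminal genes, 0 and 0 of 6 fibroblast markers, 1 and 1 of 5 endothelial and 0 and 0 of 3 leukocyte markers. Those were 4 and 4, 2 and 4, 1 and 2, 3 and 7, 1 and 4, 0 and 2, 0 and 0, 1 and 2, and 1 and 0 adjusted over the list alone. ABCC3, an efflux pump, fell (log2 -0.67 ± 0.08) and SERPINE2, a protease inhibitor, fell (-1.40 ± 0.15). Some of these lists passed when a library was left out: interferon higher without control replicate 1 or 3 or wtETV6 replicate 1 or 3 (camera adjusted p = 0.0480, 0.0468, 0.0217 and 0.0311), and ERK output lower without control replicate 1 or wtETV6 replicate 2 (0.0399 and 0.0223). Mitosis went lower without wtETV6 replicate 2 (0.00193) and higher without wtETV6 replicate 3 (0.0220).

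In E2E3, whose construct cannot be told apart from its line, the stress genes fell and the replication genes rose. DDIT3, a transcription factor induced by endoplasmic reticulum stress, fell 15.5-fold (log2 -3.95 ± 0.14), CHAC1, a glutathione-degrading enzyme of the same response, fell 21.1-fold (-4.40 ± 0.13), and HSPA5 fell from 2911 ± 289 to 210.7 ± 1.23 CPM (n = 3 dishes each). HERPUD1, a factor of endoplasmic reticulum-associated degradation, fell 13.7-fold. ACTG2, smooth muscle gamma-actin, rose 34.9-fold, from 5.089 ± 1.19 to 179.5 ± 18.5 CPM, the neuropeptide GAL 19.2-fold, the basal keratin KRT17 16-fold, from 0.6376 ± 0.249 to 10 ± 0.933 CPM, and the secreted protein OLFML3 13.5-fold. CDH16 and ARNT2, a transcription factor, rose 13.7- and 13-fold. Further falls were of KLHDC7B (47.1-fold), the stress cytokine GDF15 (24.1-fold), ADM2 (22.6-fold), INHBE (22.4-fold), the mitochondrial folate enzyme ALDH1L2 (16.1-fold) and PLAC1 (15.5-fold). In E2E3 3 counts are 0.158 to 0.168 CPM. INHBE was below that (0.09011 CPM) and PLAC1 near it (0.1989 CPM), so these 2 folds are not exact. In all 3583 genes rose and 3199 fell (43.4%), 837 and 927 at least 2-fold. Falls also outnumbered rises with a correction for GC content (3529 and 3723), which was chosen after the data were seen, with upper-quartile scaling (3307 and 3385) and by limma-trend (3230 and 3392).

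Of 39 replication genes all 39 rose in E2E3 (39 adjusted over the list alone, median log2 1.69, camera p = 4.185e-68, and 0.00531 with an estimated correlation). MCM6, a subunit of the replicative helicase, stood at log2 2.11 ± 0.10, RRM2 at 2.25 ± 0.10 and CDC45 at 1.94 ± 0.09. Of 24 stress genes 0 rose and 23 fell (23 adjusted over the list alone, median -2.05, p = 8.336e-58, and 4.076e-04 with an estimated correlation). Basal genes rose as a list, 17 higher and 3 lower of 24 (18 and 3 adjusted over the list alone, p = 4.165e-06, and 0.0340 with an estimated correlation), with the laminin chain LAMA3 at log2 1.43 ± 0.12 and the caveolin CAV1 at 2.23 ± 0.19. The other 3 calls were lost with an estimated correlation. Mitosis genes had 19 rises and 1 fall of 39 (19 and 2 adjusted over the list alone, p = 0.00198, and 0.620 with an estimated correlation), among them the kinase CDK1 (1.21 ± 0.11). Cholesterol genes had 1 rise and 12 falls of 24 (1 and 12 adjusted over the list alone, p = 0.00221, and 0.306 with an estimated correlation), among them DHCR7 (-0.94 ± 0.08) and the sterol transporter STARD4 (-3.40 ± 0.30). NF-kappaB targets had 1 rise and 8 falls of 15 (1 and 10 adjusted over the list alone, p = 0.0381, and 0.186 with an estimated correlation), among them RELB (-1.06 ± 0.14).

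The mesenchymal list was not called in E2E3 (median 0.31, camera adjusted p = 0.0601): 9 rose and 3 fell of 29 (9 and 3 adjusted over the list alone). The smooth muscle genes MYL9 and TAGLN rose (log2 1.67 ± 0.13 and 2.19 ± 0.21), as did the matrix protein TNC (1.89 ± 0.20) and the EMT factor SNAI2 (0.99 ± 0.23). FN1 at -0.20 ± 0.12 and SNAI1 at 0.02 ± 0.19 were not called. VIM, the mesenchymal intermediate filament, was called lower (-0.57 ± 0.22), but not without control replicate 1 or 2 (0.133 and 0.128) or E2E3 replicate 1, 2 or 3 (0.106, 0.0960 and 0.0816). Epithelial genes (5 and 13 of 37, also adjusted over the list alone, camera adjusted p = 0.0543) included the falling protease PRSS8 (-1.13 ± 0.13) and ELF3 (-0.80 ± 0.07), the rising EPCAM (0.31 ± 0.09), and CDH1 at -0.03 ± 0.07, not called. Rises and falls were 2 and 3 of 13 luminal genes, 3 and 10 of 27 TGF-beta response genes, 7 and 4 of 20 proteases and inhibitors, 17 and 5 of 37 interferon genes, 0 and 3 of 12 antigen presentation genes, 4 and 8 of 25 apoptosis genes, 12 and 3 of 21 tubulins and efflux pumps, 11 and 2 of 24 ERK outputs, 6 and 3 of 21 ETS factors and 14 and 8 of 29 hypoxia genes. Adjusted over the list alone they were 2 and 3, 3 and 11, 7 and 4, 17 and 6, 0 and 3, 4 and 8, 13 and 3, 11 and 2, 6 and 3, and 15 and 9. None of these lists was called, and camera put antigen presentation, apoptosis and hypoxia lower while their medians were 0.10, 0.04 and 0.26. Members named for another direction than their list's count include ABCC3, which fell (-1.79 ± 0.08) while the tubulin TUBA4A rose (1.22 ± 0.10), and DDIT4, a stress-induced inhibitor of mTORC1, which fell (-3.74 ± 0.12) while CA9, a hypoxia-induced carbonic anhydrase, rose (3.37 ± 0.36). Markers of other cell types went both ways: CD68 rose (1.43 ± 0.13) among 2 rises and 1 fall of 3 leukocyte markers (2 and 1 adjusted over the list alone), fibroblast markers had 0 and 2 of 6 (0 and 2), and endothelial markers 2 and 2 of 5 (3 and 2). Without control replicate 1 the mesenchymal, epithelial and tubulin lists passed (0.0398, 0.0398 and 0.0284). The epithelial list also passed without control replicate 3 or E2E3 replicate 1 (0.0435 and 0.0458), the tubulin list without E2E3 replicate 2 (0.0385) and ERK output without E2E3 replicate 1 (0.0469).

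In E4E3 KRT17 rose 38-fold, from 0.6376 ± 0.249 to 23.77 ± 6.82 CPM (log2 5.25 ± 0.28), the hair keratin KRT81 31.5-fold, ACTG2 42.8-fold, and TNC by log2 3.23 ± 0.20 (n = 3 dishes each). GAL rose 18.1-fold and KISS1, the kisspeptin gene, 17.1-fold. MARCHF4, a ubiquitin ligase, and the epidermal lipoxygenase ALOXE3 rose to 2.536 ± 0.762 and 3.004 ± 0.25 CPM. Their control means (0.05678 and 0.06612 CPM) are below 3 counts (0.149 to 0.198 CPM), so the fitted 40.4- and 37.2-fold are not exact. DDIT3 fell 15.7-fold, CHAC1 18.9-fold, HERPUD1 14.8-fold, DDIT4 14.8-fold, HSPA5 13.7-fold and KLHDC7B 39.2-fold. GDF15, ADM2 and ALDH1L2 fell 16.6- to 25.5-fold. INHBE fell from 2.163 ± 0.598 to 0.05492 ± 0.0531 CPM, below 3 counts (0.156 to 0.176 CPM in E4E3), so its fitted 35.3-fold is not exact. In all 3504 genes rose and 2977 fell (41.5%), 921 and 791 at least 2-fold. Without E4E3 replicate 2, 3691 rose and 3733 fell, and with the GC correction 3477 and 3687. With only E4E3 and control in the fit, fewer genes were called (2337 rose and 2149 fell). Fitted in that way, E2E3 and E4E2 had more calls than in the main fit (8031 and 8705). The E4E3 count thus depends on the spread taken from the other groups.

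All 39 replication genes rose in E4E3 (39 adjusted over the list alone, median 1.61, p = 7.965e-62, and 0.00431 with an estimated correlation), with MCM6 at log2 1.95 ± 0.10 and RRM2 at 2.15 ± 0.10. Stress genes had 0 rises and 23 falls of 24 (23 adjusted over the list alone, median -1.97, p = 1.168e-59, and 4.524e-04 with an estimated correlation). Basal genes had 19 rises and 2 falls of 24 (19 and 3 adjusted over the list alone, p = 2.102e-12, and 0.00325 with an estimated correlation), among them KRT5 (1.90 ± 0.09) and LAMA3 (1.89 ± 0.12). Of 29 mesenchymal genes 15 rose and 0 fell (16 and 0 adjusted over the list alone, p = 1.525e-05, and 0.232 with an estimated correlation). These included TAGLN (2.94 ± 0.21), SNAI2 (1.73 ± 0.22) and FN1 (0.99 ± 0.12), while VIM at -0.13 ± 0.22 and SNAI1 at -0.22 ± 0.19 were not called. Epithelial genes had 5 rises and 15 falls of 37 (5 and 17 adjusted over the list alone, p = 0.0382, and 0.353 with an estimated correlation), with PRSS8 at -1.25 ± 0.13, the junction protein TJP3 at -1.24 ± 0.14, EPCAM at 0.38 ± 0.09 and CDH1, not called, at -0.17 ± 0.07. Luminal genes had 1 rise and 4 falls of 13 (1 and 4 adjusted over the list alone, p = 0.0382, and 0.232 with an estimated correlation), led by XBP1, a factor of both luminal cells and the unfolded protein response (-2.25 ± 0.13). Cholesterol genes had 1 and 17 of 24 (1 and 18 adjusted over the list alone, p = 2.665e-06, and 0.0772 with an estimated correlation), mitosis genes 20 and 1 of 39 (20 and 1 adjusted over the list alone, p = 9.682e-04, and 0.545 with an estimated correlation), and ERK output genes 13 and 2 of 24 (15 and 2 adjusted over the list alone, p = 0.0112, and 0.353 with an estimated correlation), among them FOSL1 (1.86 ± 0.18) and the feedback inhibitor SPRY4 (1.31 ± 0.14). The epithelial call was lost without E4E3 replicate 1 or 3 (0.0547 and 0.0661) and the luminal call without E4E3 replicate 1 (0.0555).

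The lists not called in E4E3 had 16 rises and 5 falls of 37 interferon genes, 0 and 4 of 15 NF-kappaB targets, 13 and 3 of 21 tubulins and efflux pumps, 5 and 6 of 27 TGF-beta response genes, 7 and 5 of 20 proteases and inhibitors, 1 and 4 of 12 antigen presentation genes, 4 and 8 of 25 apoptosis genes, 5 and 3 of 21 ETS factors and 11 and 10 of 29 hypoxia genes. Adjusted over the list alone these were 17 and 5, 0 and 4, 14 and 3, 5 and 6, 7 and 5, 1 and 4, 4 and 8, 5 and 3, and 11 and 10. Camera put apoptosis lower at a median of 0.05, and hypoxia lower at a mean of 0.01. PLAUR, the urokinase receptor, rose (1.37 ± 0.11), ABCC3 fell (-2.13 ± 0.08), and CIITA, the regulator of MHC class II genes, fell (-1.20 ± 0.22). Leukocyte markers had 1 rise, CD68 (1.31 ± 0.13), and 1 fall of 3 (1 and 1 adjusted over the list alone), fibroblast markers 1 and 0 of 6 (1 and 0), with the collagen COL3A1 at 1.52 ± 0.41, and endothelial markers 1 and 2 of 5 (1 and 2). Without E4E3 replicate 2, 39 of 39 replication genes rose, 24 of 24 stress genes fell, basal genes had 19 and 3 of 24, mesenchymal 13 and 1 of 31, epithelial 5 and 20 of 37, luminal 1 and 7 of 14, and interferon 21 and 4 of 38. Interferon then passed (0.00529), as did NF-kappaB (0.0484). Interferon also passed without control replicate 1 or 3 (0.0429 and 0.0383), NF-kappaB without control replicate 3 (0.0443), and the tubulin list without control replicate 1 or E4E3 replicate 3 (0.0268 and 0.0141).

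Against control the most genes were called in E4E2 (7569), an order that depends on the libraries. E4E3 had 7424 without its replicate 2, and E4E2 had 6342 to 6824 with 1 E4E2 or control library left out. In E4E2 ACTG2 rose 52.4-fold, to 269.6 ± 38.7 CPM (log2 5.71 ± 0.25), KRT17 28-fold, KRT81 19.1-fold and GAL 18.2-fold (n = 3 dishes each). ALOXE3, MARCHF4 and the oxidase AOX1 rose to 3.007 ± 0.299, 2.026 ± 0.328 and 2.215 ± 0.82 CPM. Their control means (0.06612, 0.05678 and 0.1339 CPM) are below 3 counts (0.149 to 0.198 CPM). The fitted 37.3-, 32.4- and 16.1-fold are therefore not exact. KLHDC7B fell 59-fold, GDF15 28.7-fold, ADM2 23.2-fold, DDIT4 21-fold, CHAC1 15.9-fold, HERPUD1 13.4-fold, HSPA5 12.3-fold and DDIT3 12-fold, with PLAC1 and ALDH1L2 at 15.9- and 15.4-fold lower. PLAC1 was at 0.1912 ± 0.148 CPM in E4E2, near 3 counts (0.155 to 0.159 CPM), so its fold is not exact. Interferon-stimulated genes rose as a list, with 23 higher and 4 lower of 37 (23 and 5 adjusted over the list alone, median 0.70, p = 5.350e-05, and 0.315 with an estimated correlation), among them IFI6 (log2 1.71 ± 0.12), OAS3 (1.42 ± 0.13) and ISG15 (1.02 ± 0.12). In all 3920 genes rose and 3649 fell (48.4%), 933 and 1137 at least 2-fold. With the GC correction 3747 rose and 3917 fell. The share of mitochondrial ribosomal RNA was above that of every other library in these 3 dishes.

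In E4E2 all 39 replication genes rose (39 adjusted over the list alone, median 1.61, p = 1.601e-55, and 0.0112 with an estimated correlation), with MCM6 at 2.04 ± 0.10. Stress genes had 0 and 23 of 24 (23 falls adjusted over the list alone, median -1.97, p = 8.866e-49, and 9.424e-04 with an estimated correlation). Basal genes had 17 rises and 4 falls of 24 (17 and 4 adjusted over the list alone, p = 4.566e-08, and 0.0136 with an estimated correlation), with LAMA3 at 2.07 ± 0.12. Cholesterol genes had 1 rise and 17 falls of 24 (1 and 18 adjusted over the list alone, median -0.55, p = 4.566e-08, and 0.0418 with an estimated correlation), among them MVD of the mevalonate pathway (-1.65 ± 0.13) and SREBF2 (-1.46 ± 0.12). The other calls were lost with an estimated correlation. Mesenchymal genes had 14 rises and 0 falls of 29 (14 and 0 adjusted over the list alone, p = 2.443e-04, and 0.285 with an estimated correlation), among them TAGLN (8.01-fold), TNC (8.02-fold), SNAI2 (1.62 ± 0.22) and FN1 (0.68 ± 0.12), with VIM at -0.11 ± 0.21 and SNAI1 at -0.42 ± 0.19 not called. Epithelial genes had 6 and 17 of 37 (6 and 18 adjusted over the list alone, p = 0.0105, and 0.315 with an estimated correlation), with PRSS8 at -1.54 ± 0.13, EPCAM at 0.39 ± 0.09 and CDH1, not called, at -0.11 ± 0.07. Mitosis genes had 28 and 1 of 39 (28 and 1 adjusted over the list alone, p = 1.941e-06, and 0.363 with an estimated correlation), ERK outputs 14 and 2 of 24 (14 and 2 adjusted over the list alone, p = 0.00527, and 0.319 with an estimated correlation), and tubulins and efflux pumps 13 and 3 of 21 (13 and 3 adjusted over the list alone, p = 0.0340, and 0.315 with an estimated correlation). In that last list the tubulins TUBA1B and TUBA4A rose (1.22 ± 0.11 and 1.12 ± 0.10) and ABCC3 fell (-2.03 ± 0.08).

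Not called in E4E2 were luminal genes (2 rises and 6 falls of 13), TGF-beta response (6 and 9 of 27), proteases and inhibitors (7 and 5 of 20), antigen presentation (1 and 4 of 12), NF-kappaB targets (1 and 7 of 15), apoptosis (5 and 7 of 25), ETS factors (10 and 4 of 21) and hypoxia (12 and 8 of 29). Adjusted over the list alone they had 2 and 6, 6 and 10, 7 and 5, 1 and 4, 1 and 8, 5 and 7, 10 and 4, and 12 and 8. Hypoxia genes had a median of 0.17 and fibroblast markers one of 0.32, and camera put both lists lower. XBP1 fell (-1.93 ± 0.13), and the pro-apoptotic genes BBC3 and BMF fell (-2.49 ± 0.31 and -1.13 ± 0.09). Among markers of other cell types, CD68 and CD14 rose (1.26 ± 0.13 and 1.23 ± 0.35) of 3 leukocyte genes (2 and 1 adjusted over the list alone), fibroblast markers had 2 and 2 of 6 (3 and 2) and endothelial markers 1 and 1 of 5 (1 and 1). The luminal list passed without control replicate 3 (0.0445).

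**Figure D4:**
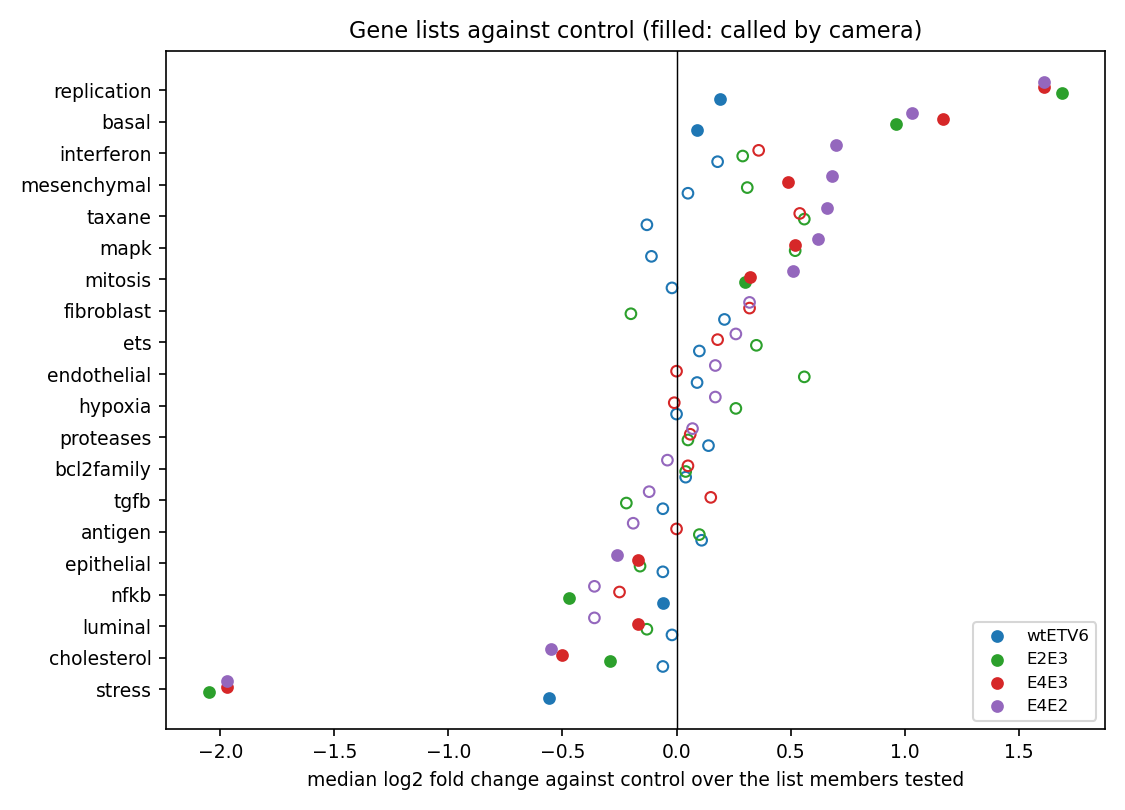
Median log2 fold change against control of the 20 lists with at least 5 tested genes, for wtETV6 and the 3 fusions, with filled points for lists called by camera at a preset correlation (taxane: tubulins and efflux pumps, mapk: ERK output, bcl2family: apoptosis). Replication lies at 1.61 to 1.69 and the stress list at -2.05 to -1.97 in the fusions, against 0.19 and -0.56 in wtETV6.

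**Figure D5:**
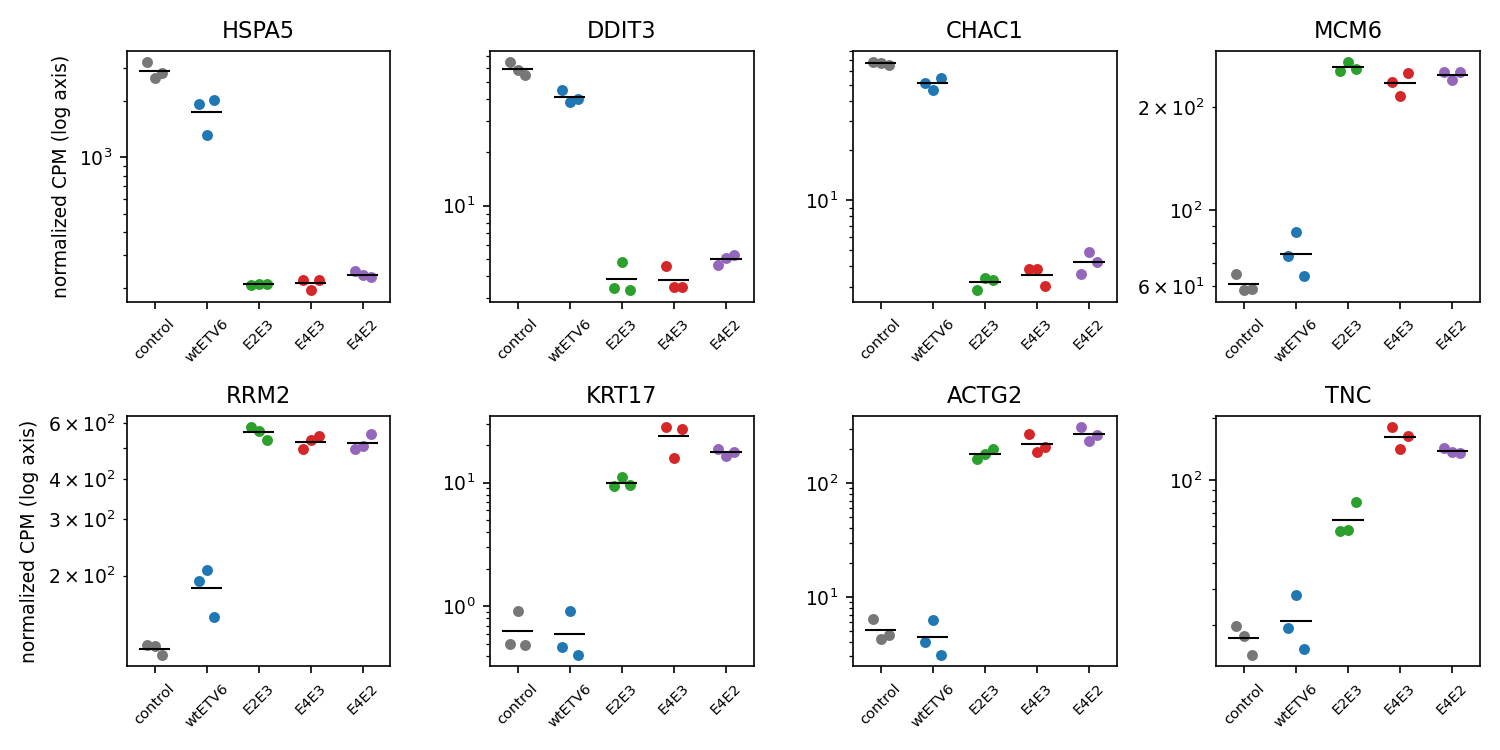
Normalized CPM on a log axis of HSPA5, DDIT3, CHAC1, MCM6, RRM2, KRT17, ACTG2 and TNC in each dish, with a line at the mean of 3 dishes. HSPA5 lies at 2911 CPM in control and at 210.7 to 236.7 in the fusions, and ACTG2 at 5.089 and at 179.5 to 269.6.

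Many of the same genes were called in the 3 fusions. In the same direction in E2E3, E4E3 and E4E2 against control, 2720 genes rose and 2252 fell, where independent lists of those sizes would share 201 and 142. The 20 simulated sets shared 0 at most. No gene differs in those sets, so they do not tell how changed lists overlap through shared control dishes. Across genes, which are not independent replicates, the log2 fold changes of fusion pairs had r = 0.89, 0.91 and 0.88. Simulated unchanged groups against 1 control had r of about 0.5 by sharing the control libraries. The covariance exceeded the simulated one by 0.457 to 0.489 for fusion pairs and by 0.071 to 0.084 for wtETV6 with each fusion (r = 0.39, 0.35 and 0.37, below the simulated r). With no control dish in common (1 dish for one group and the other 2 for the other group, 6 ways, on log2 CPM), r was 0.77 to 0.82 for fusion pairs and 0.18 to 0.28 for wtETV6 with each fusion. That split was chosen after the data were seen. Of the shared calls 3467 were also called that way against wtETV6, 1915 higher and 1552 lower, as fusion-only genes. ACTG2, KRT17, GAL, KRT81, MARCHF4, ALOXE3, ARNT2 and both transgenes rose and KLHDC7B, GDF15, ADM2, INHBE, CHAC1, ALDH1L2, DDIT4, DDIT3, PLAC1 and HERPUD1 fell most by their mean. The name fusion-only does not mean that a gene was unchanged in wtETV6. Each falling gene named was also lower in wtETV6 than in control, as GDF15 (12.3 and 4.33 CPM in control and wtETV6) and DDIT4 (372 and 188). KLHDC7B was at 102 CPM in control, 44.4 in wtETV6 and 1.71 to 2.59 in the fusions. Of the rising genes ETV6 also rose in wtETV6, while ACTG2, KRT17, GAL and ARNT2 stood no higher there than in control. Of the fusion-only genes 239 were called the same way in wtETV6 against control and 100 the opposite way. Without E4E3 replicate 2 there were 6000 shared calls and 4312 fusion-only genes. Falls outnumbered rises among the shared calls with the GC correction (2736 and 2754) and among the fusion-only genes by limma-trend (1658 and 1683).

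Against wtETV6, ACTG2 rose 40.4-fold in E2E3, 49.6-fold in E4E3 and 60.7-fold in E4E2, and GAL 27.5-, 26- and 26.1-fold. CHAC1 fell 15.9-, 14.3- and 12-fold (log2 -3.99 ± 0.13, -3.84 ± 0.13 and -3.58 ± 0.12), HERPUD1 10.8-, 11.6- and 10.5-fold, DDIT3 10.7-, 10.9- and 8.3-fold, and KLHDC7B 20.6-, 17.2- and 25.9-fold. Other named rises were of ARNT2 in E2E3 (17.2-fold), of KRT17 and MARCHF4 in E4E3 (39.4- and 32.1-fold) and of KRT17 in E4E2 (29.1-fold), and ADM2 fell 11.5- to 15.5-fold in each fusion. MARCHF4 was at 0.07207 ± 0.125 CPM in wtETV6, below 3 counts (0.152 to 0.175 CPM), so its fold is not exact. These comparisons set the fusions against a line that also overexpresses ETV6, at a level 1.39- to 2.08-fold lower. In E2E3 3208 genes rose and 2963 fell, in E4E3 3289 and 2875, and in E4E2 3563 and 3327. Without E4E3 replicate 2 it was 3425 and 3465 in E4E3, and with only E4E3 and wtETV6 in the fit 2143 and 2004. At least 2-fold were 699 and 758, 880 and 714, and 813 and 931. Falls outnumbered rises in each fusion with the GC correction (3312 and 3660, 3424 and 3701, and 3635 and 3767) and by limma-trend (2580 and 3434, 2900 and 3134, and 3288 and 3498). In E2E3 they did so with upper-quartile scaling too (2901 and 3211). Whether more genes rose or fell against wtETV6 thus depends on the method.

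All 39 replication genes rose and 23 of 24 stress genes fell in each fusion against wtETV6 (the same counts adjusted over the list alone), with medians of 1.45, 1.43 and 1.43 and of -1.54, -1.49 and -1.38 in E2E3, E4E3 and E4E2. With an estimated correlation the replication lists had adjusted p of 0.00303, 0.00452 and 0.00725, and the stress lists 0.00193, 0.00222 and 0.00461. CDC45 stood at log2 1.75 ± 0.09, 1.52 ± 0.09 and 1.66 ± 0.09. Basal genes had 15 and 2, 18 and 1, and 17 and 1 rises and falls of 24 (15 and 2, 19 and 1, and 17 and 2 adjusted over the list alone), with camera p of 2.902e-04, 5.224e-10 and 1.841e-06, and 0.0906, 0.00452 and 0.0281 with an estimated correlation. KRT5 rose (1.09 ± 0.09, 1.49 ± 0.09 and 1.32 ± 0.09) and KRT15, a basal keratin too, fell (-1.79 ± 0.13, -1.78 ± 0.13 and -2.19 ± 0.13). Mesenchymal genes had 11 and 6, 15 and 0, and 12 and 1 of 29 (12 and 6, 16 and 2, and 13 and 1 adjusted over the list alone), with p of 0.0338, 3.761e-06 and 5.490e-05, and 0.534, 0.182 and 0.254 with an estimated correlation. MYL9 rose (2.16 ± 0.13, 2.39 ± 0.13 and 2.19 ± 0.13), FN1 rose in E4E3 and E4E2 (2.83- and 2.29-fold) and was at 0.32 ± 0.12 in E2E3, not called. The E2E3 mesenchymal call was lost without wtETV6 replicate 1 or 3 (0.135 and 0.154) or E2E3 replicate 1 or 3 (0.0834 and 0.0707).

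Mitosis, ERK output, tubulins and efflux pumps, and cholesterol were called in each fusion against wtETV6 and lost with an estimated correlation. Mitosis genes had 19, 22 and 29 rises and 0 falls of 39 (21, 22 and 29 adjusted over the list alone), ERK outputs 11 and 2, 17 and 2, and 17 and 2 of 24 (12 and 2, 19 and 2, and 18 and 2), tubulins and efflux pumps 11 and 2, 12 and 3, and 12 and 3 of 21 (11 and 2, 13 and 3, and 13 and 3), and cholesterol genes 3 and 9, 2 and 16, and 2 and 16 of 24 (3 and 10, 2 and 17, and 2 and 16). In that order of lists and fusions, adjusted p with an estimated correlation was 0.534, 0.646 and 0.361, 0.421, 0.217 and 0.249, 0.421, 0.292 and 0.267, and 0.421, 0.146 and 0.0633. The growth factor-induced FOSL1 rose (1.46 ± 0.18, 1.86 ± 0.18 and 1.85 ± 0.18), the efflux pump ABCG2 rose (2.55 ± 0.24, 1.83 ± 0.25 and 2.40 ± 0.25), ABCC3 fell (-1.12 ± 0.08, -1.46 ± 0.08 and -1.36 ± 0.08), and TM7SF2 of sterol synthesis fell (-0.89 ± 0.09, -0.92 ± 0.09 and -1.37 ± 0.09). In E4E2 interferon genes (21 and 5 of 37, also adjusted over the list alone, p = 6.950e-04, and 0.361 with an estimated correlation) and epithelial genes (8 and 19 of 37, also adjusted over the list alone, p = 0.0395, and 0.361 with an estimated correlation) were called, the latter not without wtETV6 replicate 2 or E4E2 replicate 1 (0.0502 and 0.0572). CDH1 fell in E4E3 and E4E2 (-0.41 ± 0.07 and -0.34 ± 0.07) and in E2E3 (-0.26 ± 0.07), where the call was lost without E2E3 replicate 3 (0.0515). Epithelial and luminal lists, not called in E4E3 (6 and 14 of 37, and 1 and 4 of 13), passed without E4E3 replicate 2 (0.00264 and 0.0263). The remaining lists were not called, and for hypoxia in E4E3 and E4E2 (medians 0.11 and 0.22) camera pointed lower while for proteases and inhibitors (medians -0.06, -0.06 and -0.03) it pointed higher.

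E4E3 differed from E2E3, which has the shorter BCL2L14 part, in few genes. By the assumed exons, E2E3 keeps the ETV6 reading frame and E4E3 does not. Among genes higher in E4E3 were the matrix protein TNC, 2.52-fold (162.3 ± 19.7 against 64.37 ± 12.3 CPM, adjusted p = 0.00342), FN1 by log2 1.19 ± 0.13, THBS1 by 0.63 ± 0.10 and KRT17 2.37-fold (n = 3 dishes each). CYP2B7P, a pseudogene, was 8.9-fold lower, CLCA2, a chloride channel regulator, 4.96-fold, the adhesion molecule CEACAM6 3.19-fold and the chemokine CXCL17 2.87-fold lower (adjusted p = 0.00557, 1.408e-04, 1.269e-04 and 1.791e-04). The other largest changes were each lost without some library. MYO7B was 3.4-fold higher, but not called without E2E3 replicate 2 (0.0732). The phospholipase PLCB4 was higher by log2 1.62 ± 0.29, a call lost without E2E3 replicate 2 or E4E3 replicate 1 (0.0680 and 0.0541). KRT81 (1.36 ± 0.23) was lost without E2E3 replicate 1 or 2 or E4E3 replicate 1 (0.0613, 0.0594 and 0.0541), and the collagen chain COL4A4 (1.34 ± 0.23) without E2E3 replicate 1 or E4E3 replicate 1 (0.0533 and 0.0541). MUCL1 was lower by -1.82 ± 0.34, lost without E2E3 replicate 1 or 2 or E4E3 replicate 1 (0.0533, 0.104 and 0.0843). With these 6 libraries alone in the fit MYO7B, PLCB4, KRT81, COL4A4 and MUCL1 were not called (0.291, 0.269, 0.199, 0.291 and 0.338). In all 49 genes were higher and 84 lower, 11 and 16 at least 2-fold. The count was 37, 49, 42, 231 and 1343 without E2E3 replicate 1, E2E3 replicate 2, E4E3 replicate 1, E4E3 replicate 2 and E4E3 replicate 3, and 9 with these 6 libraries alone in the fit. Higher genes outnumbered lower ones without E4E3 replicate 3 (793 and 550) and with no filter on low counts (221 and 178). With these 6 libraries alone THBS1, KRT17 and CXCL17 were not called either (0.214, 0.214 and 0.0868). ETV6 itself was at log2 -0.24 ± 0.08 (adjusted p = 0.247).

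As lists, basal genes were higher in E4E3 than E2E3, with 2 higher and 0 lower of 24 (13 and 0 adjusted over the list alone, p = 1.562e-11, and 0.00728 with an estimated correlation). Mesenchymal genes had 3 and 0 of 29 (7 and 0 adjusted over the list alone, p = 2.960e-11, and 0.0986 with an estimated correlation) and cholesterol genes 0 and 1 of 24 (0 and 2 adjusted over the list alone, p = 7.929e-05, and 0.138 with an estimated correlation). Calls of 5 further lists rested on single libraries. TGF-beta response (2 and 0 of 27, 4 and 0 adjusted over the list alone, p = 7.147e-04, and 0.381 with an estimated correlation) was lost without E4E3 replicate 2 (0.383), and luminal genes (0 and 1 of 13, also adjusted over the list alone, p = 0.00819, and 0.138 with an estimated correlation) without E4E3 replicate 3 (0.252). Replication, ERK output and fibroblast markers were called at 0.0345 with 0 genes called either way, also adjusted over the list alone (0.713, 0.499 and 0.381 with an estimated correlation). Replication was lost without E2E3 replicate 2 or 3 or E4E3 replicate 1, 2 or 3 (0.0875, 0.0700, 0.0813, 0.0563 and 0.0891). ERK output was lost without E2E3 replicate 1 or E4E3 replicate 1 or 2 (0.128, 0.0813 and 0.315), and fibroblast markers without E2E3 replicate 3 or E4E3 replicate 1 or 2 (0.157, 0.200 and 0.0791). Of lists not called, hypoxia passed without E2E3 replicate 1 or E4E3 replicate 1 (0.0406 and 0.0450), and epithelial, interferon and mitosis genes without E4E3 replicate 2 (0.0164, 2.229e-05 and 0.0392). CDH1, EPCAM, VIM, SNAI1 and SNAI2 were at -0.15 ± 0.07, 0.07 ± 0.09, 0.44 ± 0.22, -0.24 ± 0.19 and 0.74 ± 0.20, none called.

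E4E2 and E4E3 share the BCL2L14 part and differ by ETV6 exon 2. By the assumed exons, E4E2 keeps the ETV6 reading frame and E4E3 does not. TSPAN1, a tetraspanin, was 1.95-fold higher in E4E2 (37.45 ± 2.21 against 19.16 ± 3.34 CPM, adjusted p = 0.00159) and GABBR2, a GABA receptor subunit, 1.6-fold lower (adjusted p = 0.00265), at n = 3 dishes each. ETV6 was higher by log2 0.58 ± 0.08 (adjusted p = 0.00919, and 0.574 with these 6 libraries alone in the fit). In all 11 genes were higher and 9 lower, 1 and 2 at least 2-fold. The count was 3279 without E4E3 replicate 3, 8 without E4E3 replicate 1, 8, 3 and 3 without E4E2 replicates 1, 2 and 3, and 0 with these 6 libraries alone in edgeR's fit, where 1094 genes had an unadjusted p under 0.05, DESeq2 calls 130 over all libraries, and neither TSPAN1 nor GABBR2 was called (0.409 and 0.442). Lower genes outnumbered higher ones without E4E3 replicate 2 (7 higher and 9 lower), without E4E3 replicate 3 (1210 and 2069), with no filter on low counts (130 and 636) and by DESeq2 (63 and 67). Interferon genes were higher (1 and 0 of 37, 7 and 0 adjusted over the list alone, p = 3.401e-11, and 0.421 with an estimated correlation), with ISG15 at 0.52 ± 0.12, not called. Mitosis genes were called higher (0 and 0 of 39, also adjusted over the list alone, p = 1.980e-05, and 0.802 with an estimated correlation). Basal and cholesterol genes were called lower (0 and 0 each; 0 and 3 of 24, and 0 and 7 of 24, adjusted over the list alone, p = 0.00720, and 0.421 and 0.659 with an estimated correlation). The basal call was lost without E4E3 replicate 1 or 3 or E4E2 replicate 2 (0.136, 0.0931 and 0.0587) and the cholesterol call without E4E3 replicate 3 (0.282). TGF-beta response passed without E4E3 replicate 3 (0.00564), and ERK output and stress genes without E4E3 replicate 2 (0.0156 and 0.0486).

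The other largest changes between E4E2 and E4E3 were each lost without some library, by edgeR's adjusted p, and with these 6 libraries alone in the fit. CEACAM6 was higher by log2 0.97 ± 0.17, not called without E4E3 replicate 1 or 2 or E4E2 replicate 1, 2 or 3 (0.128, 0.148, 0.160, 0.0984 and 0.133). DMBT1 (0.84 ± 0.13) was lost without the same 5 libraries (0.101, 0.0765, 0.0859, 0.116 and 0.0622). IFI6, an interferon-induced protein (0.75 ± 0.12), was lost without E4E2 replicate 2 or 3 (0.128 and 0.103), and STEAP4, a metal reductase (0.70 ± 0.10), without E4E3 replicate 1 or E4E2 replicate 2 or 3 (0.0549, 0.0831 and 0.0692). The matrix protein ADAMTSL4 was lower by -1.03 ± 0.18, lost without E4E3 replicate 1 or 2 or E4E2 replicate 1, 2 or 3 (0.128, 0.0612, 0.0859, 0.179 and 0.170). MARVELD1 (-0.87 ± 0.17) was lost without those 5 as well (0.128, 0.119, 0.0859, 0.179 and 0.333). SMPD3, a sphingomyelinase, was 1.99-fold lower, lost without E4E2 replicate 1, 2 or 3 (0.149, 0.128 and 0.133). The transcription factor IRX6 (-0.69 ± 0.12) was lost without E4E3 replicate 1 or 2 or E4E2 replicate 2 or 3 (0.101, 0.102, 0.190 and 0.263). With these 6 libraries alone the values of these 8 genes were 0.442, 0.303, 0.442, 0.442, 0.574, 0.574, 0.574 and 0.574 in the order given.

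E4E2 against E2E3 had higher interferon genes and lower cholesterol genes. IFI6, an interferon-induced mitochondrial protein, was 2.45-fold higher (60.1 ± 3.25 against 24.5 ± 2.84 CPM, adjusted p = 6.468e-05, n = 3 dishes each). The interferon list had 5 higher and 0 lower of 37 (15 and 0 adjusted over the list alone, p = 1.210e-18, and 0.0721 with an estimated correlation). The cholesterol list had 0 higher and 4 lower of 24 (0 and 13 adjusted over the list alone, median -0.25, p = 2.822e-15, and 0.0183 with an estimated correlation). Mesenchymal genes had 3 and 0 of 29 (8 and 0 adjusted over the list alone, p = 8.480e-09, and 0.0979 with an estimated correlation), and basal genes 1 and 0 of 24 (5 and 1 adjusted over the list alone, p = 1.966e-04, and 0.0973 with an estimated correlation). ERK outputs had 1 and 0 of 24 (2 and 0 adjusted over the list alone, p = 2.738e-04, and 0.247 with an estimated correlation), mitosis genes 0 and 0 of 39 (also adjusted over the list alone, p = 1.710e-07, and 0.443 with an estimated correlation), and luminal genes, lower, 0 and 0 of 13 (0 and 2 adjusted over the list alone, p = 0.0167, and 0.152 with an estimated correlation), which was lost without E2E3 replicate 2 (0.0501). FN1 was higher by 0.88 ± 0.12, a call lost without E2E3 replicate 1 or E4E2 replicate 3 (0.0648 and 0.0632). Epithelial and NF-kappaB genes passed without E4E2 replicate 2 (0.0429 and 0.0281), and TGF-beta response and fibroblast markers without E4E2 replicate 3 (0.0445 and 0.0355). In all 27 genes were higher and 44 lower, 7 and 8 at least 2-fold. The count was 3, 13 and 28 without E2E3 replicates 1, 2 and 3 and 12, 8 and 2 without E4E2 replicates 1, 2 and 3, and 1140 with these 6 libraries alone in the fit. Without E4E2 replicate 3, 1 was higher and 1 lower.

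Of the 10 largest changes between E4E2 and E2E3, 5 higher and 5 lower, the other 9 were each lost without some library, by edgeR's adjusted p. For 4 of them every one of the 6 removals ended the call, with values in the order of E2E3 replicates 1, 2 and 3 and E4E2 replicates 1, 2 and 3. These were the interferon-induced IFI44 (log2 1.74 ± 0.38: 0.245, 0.184, 0.106, 0.130, 0.118 and 0.268) and MX1 (1.60 ± 0.26: 0.173, 0.0840, 0.102, 0.0847, 0.112 and 0.105), the growth factor EREG (1.40 ± 0.30: 0.259, 0.156, 0.0792, 0.0759, 0.213 and 0.192) and, lower, the matrix protein SMOC1 (-1.76 ± 0.36: 0.150, 0.160, 0.0893, 0.139, 0.0873 and 0.249). TNC (1.11 ± 0.18) was lost without E2E3 replicate 1 or 2 or E4E2 replicate 1, 2 or 3 (0.150, 0.0981, 0.0759, 0.0876 and 0.103), and ZNF22 (-1.64 ± 0.30) without the same 5 (0.0852, 0.0852, 0.108, 0.0993 and 0.0632). CYP2B7P (-3.03 ± 0.51) was lost without E2E3 replicate 1 or 2 or E4E2 replicate 1 or 3 (0.0852, 0.0728, 0.0625 and 0.0632). The selenium carrier SELENOP (-1.71 ± 0.24) was lost without E2E3 replicate 1 or E4E2 replicate 2 or 3 (0.0661, 0.0605 and 0.0632), and the sodium channel subunit SCNN1B (-1.65 ± 0.30) without E2E3 replicate 1 or 3 or E4E2 replicate 2 or 3 (0.150, 0.0765, 0.0876 and 0.111).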

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

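The tests of scaling, of ETV6 alone, of depth, of wrong labels and of the coding length, and the gene examples below, were chosen after the result was seen. The tests of starvation genes, of GC content, of the second annotation row and of other splits were fixed ahead of their results.

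Some genes went opposite ways in wtETV6 and in a fusion, each against control, with the difference between them called too: 126 genes for E2E3, 132 for E4E3 and 152 for E4E2. The difference was called for every gene that went opposite ways, so that condition removed none. More genes went the same way as in wtETV6: 347, 318 and 321 rose in both and 334, 330 and 336 fell in both. BCAS1 rose in wtETV6 (log2 1.37 ± 0.18) and fell in E2E3, E4E3 and E4E2 (-1.75 ± 0.21, -1.85 ± 0.21 and -1.80 ± 0.21), with differences of -3.11, -3.22 and -3.17. CYP4F8, a cytochrome P450, rose in wtETV6 (1.15 ± 0.17) and fell in E4E3 and E4E2 (-2.08 ± 0.20 and -2.18 ± 0.20). ATP6V1B1, a proton pump subunit, rose (1.08 ± 0.16) and fell in E4E3 (-1.85 ± 0.18). Between fusions 1 gene did so: MYO7B, at -0.84 ± 0.33 in E2E3 and 0.92 ± 0.29 in E4E3 (difference 1.77 ± 0.31). Its call in E2E3 was lost without control replicate 1, 2 or 3 (edgeR adjusted p = 0.0649, 0.117 and 0.0794) or E2E3 replicate 1, 2 or 3 (0.0554, 0.168 and 0.0696). In E4E3 it was lost without control replicate 1 or E4E3 replicate 2 (0.0588 and 0.0840), and the difference was lost without E2E3 replicate 2 (0.0732) or with only E2E3 and E4E3 in the fit (0.291). The E2E3 call was also lost with only E2E3 and control in the fit (0.0540). With 3 dishes per group, no formal outlier test was run, and E4E3 replicate 2 is described by its deviations below.

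The stress genes fell in the 3 fusions. Scaling is argued against, since it moves all genes of a library alike, and the list's median less that of all genes was -1.97 (E4E2, SE 0.25) or lower in each fusion. ETV6 overexpression alone stays open: the list fell in each fusion against wtETV6 (largest adjusted p 0.0046 by camera with an estimated correlation), but it also fell in wtETV6 (median -0.56), and ETV6 RNA was 1.39- to 2.08-fold higher in the fusions than there. Nutrient or growth factor shortage in the control and wtETV6 dishes stays open, and its test came out as shortage would have it in the control dishes, with 20 starvation and FOXO genes at medians of -0.53, -0.45 and -0.71 in E2E3, E4E3 and E4E2 (median SE 0.19, 0.22 and 0.23) and at -0.06 in wtETV6. A direct or indirect effect of the fusions stays open beside it, since each construct has 1 line and the age of the medium in each dish is not given in the sources used here. The same limits hold for the replication genes, for which no cause was tested.

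E4E3 replicate 2 lay apart from its group, and a trend with GC content as the whole cause is argued against: the SD over 12389 genes of its deviation from the other E4E3 libraries was 0.472 before and 0.365 after a correction for GC content, above the highest of the other libraries (0.34, E4E3 replicate 3). GC content may account for part of it, with rho of 0.55 in replicate 2 and -0.57 in replicate 3, which lies off the other way. Low depth and a control or wtETV6 dish under the wrong label are argued against, as its total count ranked 14 of 15 from the lowest and it had 299 BCL2L14 counts. An E2E3 or E4E2 dish under the wrong label is argued against as the whole cause, since its deviation from the E2E3 mean (SD 0.448) and the E4E2 mean (0.521) was above that of any of their own libraries (0.23 and 0.25). Its deviation from its own group (0.472) cannot be set against 0.448. It is taken from 2 dishes, of which replicate 3 lies off the other way. TNC and FN1 of the dish (141.8 and 285 CPM) were above every E2E3 dish (at most 78.54 and 162.5). Its ETV6 (1743 CPM) was below every E4E2 dish (at least 2388.8). Its KRT17 (15.91) was nearer to E4E2 (16.27 to 18.68) than to the other E4E3 dishes (28.11 and 27.28). These few picked genes do not settle which fusion the dish carries. A different state of it stays open beside a wrong label, and no biological explanation was tested.

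BCL2L14 counts lay far below ETV6 counts in the fusion libraries. The shorter coding part is argued against as the whole cause, since the highest group ratio was 1.33% (E4E3, 0.81% without replicate 3) where lengths would give 36.3 to 56.8%. Reads lost to a second placement of the gene cannot be told apart from low counts for another reason: 65% of 1247 protein-coding symbols with a second row were under 1 CPM, against 35.9% of 17689 without, and such symbols differ in kind. The strand setting and the makeup of the inserted sequence also stay open, untested, and no biological explanation was tested.

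Each comparison of 2 groups has 10 splits of its 6 libraries into 3 and 3, of which 1, the real one, called as many genes. That is too few for a share under 0.05. The real counts and the highest of the other splits were 1083 and 1 for wtETV6 against control, 6782 and 0 for E2E3, 6481 and 0 for E4E3, and 7569 and 0 for E4E2. Against wtETV6 they were 6171 and 0, 6164 and 0, and 6890 and 0 in the same order. Between fusions they were 133 and 26 for E4E3 against E2E3, 20 and 1 for E4E2 against E4E3, and 71 and 0 for E4E2 against E2E3. All are edgeR counts. At an unadjusted p under 0.05 the highest other splits had 700, 427, 2662, 672, 573, 3141, 673, 3599, 3589 and 672 genes, with the 4 highest in the comparisons that hold E4E3, whose dishes lie apart. For the shared calls and the fusion-only genes, 60 regroupings of the 15 libraries into 5 groups of 3 were drawn, the real one included. The real values of 4972 and 3467 were reached by 1 of 60, and the highest other was 0. A regrouping that mixes fusion dishes with control or wtETV6 dishes widens the spread within groups, so low counts follow from its design. The dishes of a group share 1 line as far as the labels tell, so the regroupings cannot exclude chance differences between lines.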

How the results depend on the processing

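The GC correction and the summing of annotation copies were chosen after the data were seen. Causes of the changes below were not tested, except that stricter thresholds call fewer genes by construction.

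Of the genes called, a threshold of 2-fold left 162 for wtETV6 against control, 1764, 1712 and 2070 for E2E3, E4E3 and E4E2, 1457, 1594 and 1744 for these against wtETV6, 27, 3 and 15 for E4E3 against E2E3, E4E2 against E4E3 and E4E2 against E2E3, 1107 shared calls and 628 fusion-only genes. An adjusted p under 0.01 left 503 for wtETV6 against control and 49, 5 and 9 between the fusions in that order. With only the compared groups in the fit there were 2059 for wtETV6 and 9, 0 and 1140 between the fusions (the 0 by edgeR, with 1094 genes at an unadjusted p under 0.05). DESeq2 called 284, 130 and 212 between the fusions and no filter gave 399, 766 and 287. The GC correction gave 1648 for wtETV6, 329 for E4E3 against E2E3 and 166 for E4E2 against E2E3. A replicate block gave 10 for E4E2 against E4E3 and 24 for E4E2 against E2E3, though correlations of same-numbered dishes (-0.22 to 0.13) do not pair them. Limma-trend gave 44 for E4E2 against E2E3. Other settings stayed within 1.5 times the counts in the report.

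Leaving out each library gave 570 to 845 for wtETV6 against control, 5662 to 5977, 5522 to 7424 and 6342 to 6824 for the fusions, 4813 to 5614, 4951 to 6890 and 5608 to 6362 for these against wtETV6, and 37 to 1343, 3 to 3279 and 2 to 28 between the fusions. Shared calls were 4178 to 6000 and fusion-only genes 2853 to 4312.

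Lists called by camera numbered 4 for wtETV6, 6, 9 and 10 for the fusions, 8, 8 and 10 against wtETV6 and 8, 4 and 7 between the fusions. With an estimated correlation they were 1, then 3, 3 and 4, then 2, 3 and 3, then 1, 0 and 1. By fry they were 16, 17 and 17 for the fusions, 16, 14 and 16 against wtETV6, and 5 and 2 for E4E3 against E2E3 and E4E2 against E4E3. A filter of 1 CPM left 2 for wtETV6. Leaving out each library gave 3 to 6, 6 to 9, 7 to 11, 10 to 11, 7 to 8, 8 to 10, 9 to 10, 6 to 8, 3 to 6 and 6 to 9. Of 200 list tests, 74 called, RLE scaling changed 0 calls and a replicate block lost 1. The GC correction lost 3 and gained 10, fry lost 9 and gained 48, and an estimated correlation lost 53. With the filter of 1 CPM, 4 of 73 were lost and 1 gained in 190 tests.

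Of the named genes' values under alternatives 11741 kept direction and side of the threshold, 419 kept direction without passing, and 3 reversed. HLA-B in E4E2 against wtETV6 was at -0.107 with copies summed, and SELENOP in E2E3 against control at 0.015 without control replicate 3 and 0.025 without E2E3 replicate 3. Depth limits genes of few counts: CDH2, ZEB1, ZEB2 and TWIST1 were not tested.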

Other observations

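The genes TXNIP and ARRDC4 were chosen after their values were seen. TXNIP, an arrestin induced by glucose, was at 8.05 ± 0.494 CPM in control, 15.8 ± 0.491 in wtETV6, and 100 ± 7.88, 101 ± 14 and 98 ± 6.7 in E2E3, E4E3 and E4E2. ARRDC4, which is induced by glucose too, was at 9.37 ± 0.882 in control, 8.94 ± 0.344 in wtETV6, and 19 ± 1.11, 23.2 ± 5.74 and 20.4 ± 0.301 in the fusions. Of 20 starvation and FOXO genes, 2 rose and 14, 12 and 14 fell in E2E3, E4E3 and E4E2 against control, with camera p of 6.030e-06, 1.150e-06 and 2.070e-07, and 0.0194, 0.0123 and 0.0105 with an estimated correlation. In wtETV6 2 rose and 0 fell (0.852 and 0.912).

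Among apoptosis genes HRK, a pro-apoptotic BH3 gene, fell in each fusion against control (log2 -0.93 ± 0.13, -1.07 ± 0.13 and -0.92 ± 0.13). Among ETS factors ERG rose in E2E3 and E4E3 (1.33 ± 0.20 and 1.31 ± 0.20) and in E4E2 (adjusted p by edgeR = 7.790e-06), and ELF4 rose (0.66 ± 0.07, 0.75 ± 0.07 and 0.72 ± 0.07). Among TGF-beta response genes KLF10 rose (0.80 ± 0.07, 0.77 ± 0.07 and 0.84 ± 0.07) and TGIF1, a repressor in that pathway, fell (-0.81 ± 0.07, -0.80 ± 0.07 and -0.87 ± 0.07).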
